A study of Mus musculus with 2 samples.

How the data were processed

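Livers of mouse embryos (Mus musculus, strain B6NCrl, both sexes mixed) were collected at embryonic day 12.5, and histone H3 trimethylated at lysine 4 (H3K4me3) was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels, replicate 1 was made from the livers of 120 embryos and replicate 2 from those of 88 embryos, and both are biological replicates. The series therefore holds 2 samples of 1 group, and no comparison between groups exists. The labels state that each sample is a pool, so a difference between the replicates is a difference between pools and not between animals.

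The files analysed were 4 lists of peaks in narrowPeak format, 1 per replicate and 2 for the whole series, with coordinates on mm10 (GRCm38) per the file descriptions. The list of each replicate was made by the authors from the alignments of that replicate and 1 further file. The pooled list was called by the authors on both replicates together, and the replicated list was derived from the lists of replicate 1, replicate 2 and the pool, per the file descriptions. The peak caller, its threshold and the aligner are not given in the sources used here. The deposited signal value of a peak is the authors' own enrichment measure for that peak, and what it is relative to is not stated. The deposited lists also carry a −log10 p-value and a −log10 q-value for each peak, made by the authors. Signal values and q-value scores were used to describe, rank or filter peaks within a list and to match random lists on signal, and signal values were compared between lists only through ranks, as Spearman's rho between the replicates. Read counts per library were not in the peak lists, so the depth of each sample is unknown and no interval that needs it is given.

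The lists held 30882 peaks for replicate 1, 33964 for replicate 2, 34947 in the pool and 25640 replicated peaks. Peaks on scaffolds outside chromosomes 1 to 19, X and Y numbered 16, 15, 21 and 11 in these lists and were left out of all comparisons. No peaks of a list overlapped each other. The lowest −log10 p-value in the deposited lists was 2.02 in replicate 1 and 2.00 in replicate 2, while −log10 q-values went down to 0.172 and 0.195, so peaks with weak scores are part of the lists. All 25629 replicated peaks on these chromosomes were also in the pooled list.

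Start sites were those of all transcripts of the 21911 protein-coding gene symbols in GENCODE release M21 on the same build, and all peaks and genes lay inside the reference chromosome lengths. A gene was called marked when a region of the list shared at least 1 bp with the window of 1 kb on either side of any of its start sites. Domains were regions of a list joined when 1 kb or less apart, and the width given for a gene is that of the widest domain at any of its start sites. A gene can be marked through a domain that starts at a neighbour. The signal value given for a gene is the highest among the regions, not joined, within 1 kb of any of its start sites. The widths in the lists of the replicates were computed in the same way, and a mean ± SD over n = 2 is over these lists, with a width of 0 where a gene was unmarked. The widest domain at a gene can be a different region in each list, and where the replicates' domains did not overlap their widths are given singly.

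The 20 gene lists were fixed before the data were examined, as were the tests, the alternatives, and the rule for the genes named. Ahsp was not in the annotation, C5 was matched to Hc, and H19, Meg3 and Kcnq1ot1 are noncoding and stayed outside the tests. Alas2, Dlk1 and Hnf1b each stand in 2 lists and count in both. The rule named, for each list, the 3 members with the widest replicated domain and up to 3 unmarked members in alphabetical order, the genes at the 20 widest domains (up to 4 per domain), the genes at the 5 replicated regions of highest signal value, and, for each replicate, the 5 genes marked only there with the highest signal value. The share of marked genes in a list was compared with that of all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. Intervals on shares are exact 95% binomial intervals over genes. Genes are not biological replicates, so p-values and intervals describe the list in these libraries and not the variation between embryos. A list's median domain width was placed among the medians of 10000 random lists of as many marked genes, and called above or below where it passed the 97.5 or 2.5 percentile. These calls were not adjusted over the 20 lists. List members among the widest 5% of marked genes were counted and tested with Fisher's exact test in the same way. Overlap between lists of regions was set against 100 random placements of the regions on the same chromosomes.

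Alternatives were an overlap of at least 50% of both regions, only peaks with a q-value score of at least 5, regions joined at 1 kb before comparing replicates, start site windows of 500 bp and 2.5 kb, the outermost start site of each gene alone, the list of each replicate alone in place of the replicated list (which leaves out the other replicate), the pooled list, domains not joined or joined at 3 kb, the signal value in place of width, and random lists matched to the list in 10 bins on the observed over expected CpG content of the 1000 bp around the outermost start site, whose p is a permutation p over 10000 lists with the same adjustment. An analysis restricted to domains of a single gene, those that were the widest domain of only 1 protein-coding gene, was chosen after seeing the data. Such a domain can still hold the start of a noncoding gene or of a gene with a wider domain elsewhere.

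The code was tested on simulated data. With 79.9% of 19075 simulated regions shared, 79.9% were recovered. On the 21911 real gene symbols with simulated marks at a background of 66%, lists of 20 genes marked at 20% were called in 96.7% of cases, lists marked at 97% in 88.3%, and lists marked at the background rate in 0.714%. For domain width, 4.71% of lists without a difference and 98.3% of lists with domains 2.5 times as wide fell outside the central 95% of random lists. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, samtools 1.23.1, and minimap2 2.31-r1302. The last was used to find near-identical copies of promoters on the same chromosomes, with at least 80% of the 1000 bp matching at 98% identity or more.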

Results

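H3K4me3, a histone modification found mainly at active and CpG-rich promoters, was mapped in mouse liver at embryonic day 12.5 in 2 biological replicates, pools of 120 and 88 embryos. At this age the liver is a site of blood formation as well as the developing hepatic organ. On chromosomes 1 to 19, X and Y the authors' lists held 30866 regions covering 36.9 Mb in replicate 1, 33949 covering 40.4 Mb in replicate 2 and 25629 covering 41.5 Mb in the replicated list, with median widths of 765, 708 and 1273 bp. The depth of the libraries is unknown from these lists. The design holds a single group, so the comparisons are between gene groups within the tissue and between the replicates.

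The mark lay mostly at gene starts. Of the 25629 replicated regions, 15644 (61.0%) were within 1 kb of a start site of a protein-coding gene, against a mean of 6.53% and a maximum of 6.88% over 100 random placements. These regions took 80.4% of the marked bases, with a median width of 1954 bp and a median signal value of 36.7. Starts of long noncoding RNAs accounted for another 875 regions (3.41%), other annotated starts for 439 and exons away from a start for 1453 (5.67%). Introns held 3910 regions (15.3%) with a median width of 548 bp and a median signal value of 4.34, and 3308 (12.9%) were intergenic. Counted by gene, 14526 of 21911 protein-coding genes (66.3%) carried a replicated region, 14515 a region in the list of replicate 1 and 14686 in that of replicate 2.

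Genes of the red cell lineage were marked more often than other genes. In the erythroid list 27 of 29 genes carried a replicated region (93.1%, 95% interval 77.2 to 99.2), against 66.3% of other genes, with an adjusted p of 0.00418 by Fisher's exact test. They included Ank1, the ankyrin of the red cell membrane skeleton, Lmo2, a LIM-domain partner of erythroid transcription factors, and Tal1, a transcription factor needed for blood formation. The unmarked members were Hba-x and Hbb-y, the embryonic globins of primitive red cells, which carried regions of 0.193 and 0.183 kb in the list of replicate 2 and none in that of replicate 1. The share expected of promoters with like CpG content was 40.5% (adjusted permutation p = 0.00133). Of the heme synthesis genes 14 of 15 were marked (93.3%, exact adjusted p = 0.0497), among them Fech, which inserts iron into protoporphyrin, Hmbs and Cpox. The unmarked member was Slc25a37, the mitochondrial iron importer of erythroid cells, whose promoter sequence has an identical copy of 1001 bp on chromosome 14 from 69502862 to 69503862. The call on heme genes was lost with promoters matched on CpG content (74.1% expected, adjusted permutation p = 0.066), with a 500 bp window (exact adjusted p = 0.0537) and with the pooled list (exact adjusted p = 0.074).

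Blood stem and progenitor genes were also marked more often than other genes, while the lists of other blood lineages did not pass the main test. Of the progenitor list 19 of 20 genes were marked (95%, exact adjusted p = 0.00996), with Lyl1, Runx1 and Meis1, transcription factors of blood progenitors, at the widest domains (that of Lyl1 is shared with neighbouring genes). Hoxa10 was the unmarked member, although each replicate list held a narrow region at one of its start sites, 0.224 kb in replicate 1 and 0.321 kb in replicate 2, at places that do not overlap. Of the megakaryocyte list 11 of 15 genes were marked (exact adjusted p = 0.817), including Itga2b and Itgb3, the integrin subunits of platelets, and Nbeal2, while Clec1b (0.263 kb in replicate 2 alone), Gp6 and Ppbp were unmarked. Macrophage and granulocyte markers were marked in 9 of 20 cases (45%, exact adjusted p = 0.0812), with Vcam1, Mpo and Prtn3 marked and Adgre1 (0.336 kb in replicate 1 alone), C1qa and C1qb unmarked. Lymphoid markers were also marked in 9 of 20 cases (exact adjusted p = 0.0812), with Gata3, Tcf7 and Lck marked and Cd19, Cd3e and Cd3g unmarked. Against promoters of like CpG content the megakaryocyte share of 73.3% compared with 39.5% expected and passed the threshold (adjusted permutation p = 0.010). The macrophage share became a lower share past the threshold at a q-value score of at least 5 (40%, exact adjusted p = 0.0381), and the lymphoid share did so with outermost start sites alone (25%, exact adjusted p = 0.00265). Against promoters of like CpG content neither share was lower, with 28.3% expected of the macrophage list (adjusted permutation p = 0.177) and 44.2% of the lymphoid list (adjusted permutation p = 1), and with the pooled list the macrophage share was 65% (exact adjusted p = 0.903).

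Among the hepatic lists, plasma protein genes and liver transcription factors were marked more often than other genes, and genes of mature hepatocyte metabolism less often. Of the plasma protein genes made by fetal liver parenchyma 20 of 22 were marked (90.9%, interval 70.8 to 98.9, exact adjusted p = 0.0275), including Vtn (in a domain shared with a neighbouring gene), Dlk1 and Rbp4, the plasma carrier of retinol, and the unmarked members were Apoc3 and Fetub. The share expected of promoters with like CpG content was 39.9% (adjusted permutation p = 0.00133). Of the liver transcription factors 19 of 20 were marked (95%, exact adjusted p = 0.00996), among them Gata6, Prox1 and Onecut2. Nr1h4, the bile acid receptor FXR, was the unmarked member and carried a region of 0.175 kb in the list of replicate 2. In the adult list 8 of 30 genes of mature hepatocyte metabolism were marked (26.7%, interval 12.3 to 45.9, exact adjusted p = 1.94e-04). Glul (in a domain shared with a neighbouring gene), Gls2 and Fah were marked, and Abcb11, the bile salt export pump, Arg1, the urea cycle arginase, and Baat, which conjugates bile acids, were not. Of the clotting and complement genes 16 of 28 were marked (57.1%, exact adjusted p = 0.377), including Serpinf2, Pros1 and C8a and without C4b, C6 and C8b. Promoters of these 2 lists are poor in CpG (median observed over expected 0.217 and 0.204). Against promoters of like CpG content the adult hepatocyte share was no longer past the threshold (36.0% expected, adjusted permutation p = 0.363), and the clotting and complement share turned to a higher one (25.8% expected, adjusted permutation p = 0.0048). With the pooled list, in which 14837 of 21911 genes were marked, the latter was 67.9%, nearly level with that of other genes (exact adjusted p = 1). The call on plasma protein genes was lost with a 500 bp window (86.4%, exact adjusted p = 0.0794).

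Markers of other cell types of the liver did not pass the main test. Endothelial genes were marked in 15 of 17 cases (88.2%, exact adjusted p = 0.0943), with Egfl7, Esam and Kdr, the main receptor for vascular endothelial growth factor, marked and Emcn and Lyve1 unmarked. The lists of replicate 2 alone and of the pool held all 17 (100%, exact adjusted p = 0.00282 and 0.00536), and the CpG-matched comparison also passed the threshold (55.2% expected, adjusted permutation p = 0.0048). At Emcn and Lyve1 the regions of replicate 2 were narrow (0.228 and 0.237 kb) with low signal values (3.20 and 2.89), and replicate 1 had none. Of the mesenchymal and mesothelial genes 14 of 20 were marked (exact adjusted p = 0.817), including Hand2, Lhx2 and Pdgfra and without Acta2, Dcn and Lum. This share was 70%, and without replicate 2 it was 65% (13 of 20 genes), slightly lower than that of other genes. Of the bile duct genes 7 of 12 were marked (exact adjusted p = 0.615), including Hnf1b, Sox9 and Jag1 and without Cldn4, Krt23 and Krt7.

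Among genes of organs other than liver, muscle and germline genes were marked less often than other genes, and neuronal and patterning genes did not pass the main test. Only 4 of 20 muscle genes were marked (20%, exact adjusted p = 1.94e-04). They were Mylpf and Ckm, each in a domain that also holds the start of a neighbouring gene, Ryr2, and Tnni3, which was named after its values were seen. Acta1, Actc1 and Myf5 were unmarked. Of the germline genes 3 of 18 were marked (16.7%, exact adjusted p = 1.94e-04), namely Gdf9, again in a domain shared with a neighbour, Spo11 and Dazl, while Bmp15, Ddx4 and Hormad1 were unmarked. The muscle call was lost with matched CpG content (39.8% expected, adjusted permutation p = 0.0717) and the germline call was not (63.5% expected, adjusted permutation p = 0.00133). Neuronal genes were marked in 17 of 20 cases (85%, exact adjusted p = 0.121), with Slc17a7, Neurog2 and Nefm marked and Dcx, Slc17a6 and Stmn2 unmarked. Patterning transcription factors of other organs were marked in 25 of 30 cases (83.3%, exact adjusted p = 0.0812), with Gbx2, Irx3 and Six1 marked and Lhx3, Nkx2-5 and Otx2 unmarked. Otx2 carried 0.210 kb in the list of replicate 1 and 0.175 kb in that of replicate 2, at places that do not overlap, and Nkx2-5 0.275 kb in that of replicate 2 alone. This share passed the threshold with a 2.5 kb window, with the pooled list and in the list of each replicate alone, at 86.7% in replicate 1 (exact adjusted p = 0.0381) and 93.3% in replicate 2 (exact adjusted p = 0.00282). Against promoters of like CpG content its direction turned, with 83.3% marked and 93.6% expected (adjusted permutation p = 0.0766).

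All 25 housekeeping genes (exact adjusted p = 2.64e-04) and all 20 cell cycle genes (exact adjusted p = 0.00184) were marked, among them Rpl13a, Ywhaz and Rplp0 in the first list and Pcna, Aurka and Ccne1 in the second. Against promoters of like CpG content 89.9% and 97.7% were expected, and neither list passed the threshold after adjustment (adjusted permutation p = 0.0717 and 1). All members were marked already, so little room was left for a higher share, least of all for cell cycle genes. Of the imprinted protein-coding genes 14 of 15 were marked (93.3%, exact adjusted p = 0.0497), including Igf2, Peg3 and Grb10, and Ndn was not. With outermost start sites alone the imprinted share was 73.3% (exact adjusted p = 0.488), and it also missed the threshold with a 500 bp window (exact adjusted p = 0.0537) and with the pooled list (exact adjusted p = 0.074).

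**Figure D1:**
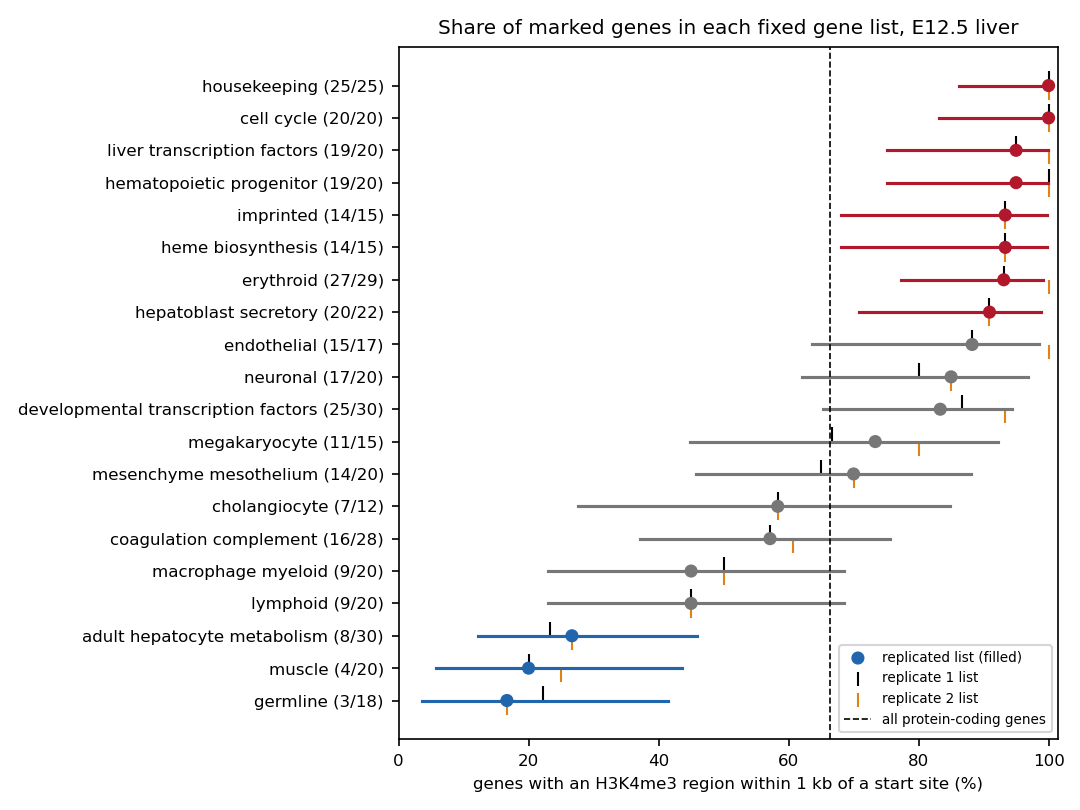
Share of genes (%) with an H3K4me3 region within 1 kb of a start site for each of the 20 fixed lists, with marked over annotated genes in brackets. Points are the replicated list with exact 95% binomial intervals over genes, ticks are the lists of each replicate alone, and the dashed line is the 66.3% of all protein-coding genes; red and blue lists had a higher or lower share past the threshold, from 100% for housekeeping genes to 16.7% for germline genes.

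Of the 20 lists, the erythroid and heme genes had the widest median domains. The median domain was 7.92 kb at the 27 marked erythroid genes and 7.31 kb at the 14 marked heme genes, against 2.36 kb over all marked genes, and both lay above all 10000 random lists. Progenitor genes (4.61 kb), liver transcription factors (4.56 kb), cell cycle genes (4.25 kb) and housekeeping genes (4.19 kb) were also at the 100th percentile. The domain at Fech spanned 13.5 kb in the replicated list and 11.7 ± 2.59 kb in the replicates (SD, n = 2), that at Gata6 9.48 kb and 9.16 ± 0.426 kb, and that at Runx1 8.22 kb and 7.87 ± 0.0255 kb. Plasma protein genes had a median of 2.41 kb, at the 55.2 percentile of random lists. Domains were narrower than in random lists at clotting and complement genes (1.11 kb, percentile 0.01), neuronal genes (1.31 kb, percentile 0.09), patterning factors (1.76 kb, percentile 1.57) and the 3 marked germline genes (0.844 kb, percentile 1.27). These percentiles were not adjusted over the 20 lists, so those of 1.57 and 1.27 are weak evidence. The patterning factors lay inside the central 95% with domains of a single gene (percentile 8.99) and, just, without replicate 2 (percentile 2.53). The remaining lists lay within the central 95%, with medians of 3.10 kb for imprinted, 2.12 kb for endothelial, 2.09 kb for lymphoid, 2.07 kb for mesenchymal, 1.93 kb for megakaryocyte, 1.84 kb for macrophage, 1.72 kb for adult hepatocyte, 1.55 kb for bile duct and 1.37 kb for muscle genes. Several left it under an alternative: without replicate 2 macrophage genes (0.896 kb, percentile 0.065) and imprinted genes (3.05 kb, percentile 97.6), with the pooled list adult hepatocyte (0.890 kb, percentile 0), macrophage (1.13 kb, percentile 0.09), bile duct (1.29 kb, percentile 0.705) and muscle genes (1.18 kb, percentile 2.33), and with domains not joined macrophage genes (0.961 kb, percentile 0.09) and imprinted genes (percentile 98.5).

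Width and height of the mark did not rank the lists alike. The median signal value of the marked erythroid genes was 49.0, at percentile 51.5 of random lists, and that of the heme genes was 64.8, at percentile 97.3. Liver transcription factors (18.6, percentile 0.61) and progenitor genes (18.0, percentile 0.53), which were wide, had low signal values. Plasma protein genes had a median of 9.10 and endothelial genes one of 7.72, at percentiles 0 and 0.02, while cell cycle genes (67.2) and housekeeping genes (66.2) were high at percentile 99.8 each.

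**Figure D2:**
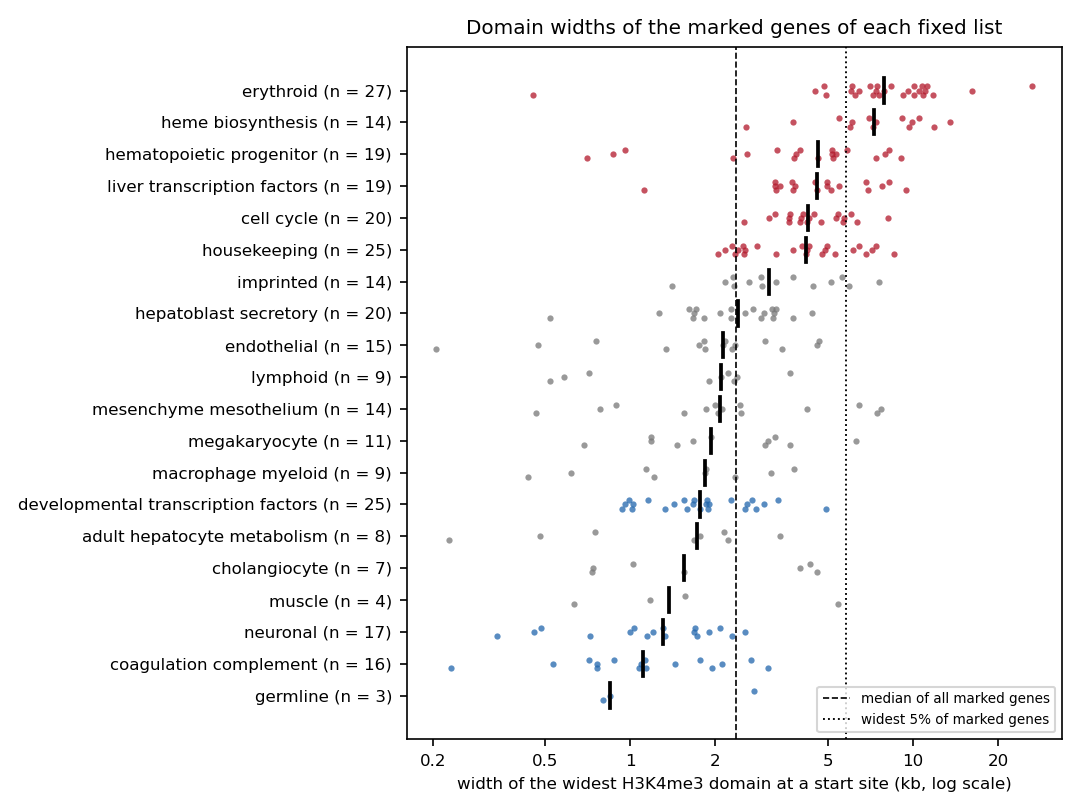
Width in kb on a log axis of the widest H3K4me3 domain at a start site for each marked gene of the 20 lists in the replicated list, with 1 point per gene and a black bar at the list's median. The dashed line is the 2.36 kb median of all marked genes and the dotted line the 5.78 kb limit of the widest 5%; red and blue lists had medians above or below the central 95% of random lists, from 7.92 kb for erythroid to 0.844 kb for germline genes.

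Erythroid and heme genes were frequent among the widest domains. Of the marked erythroid genes 23 of 27 (85.2%) were among the 728 genes with domains of at least 5.78 kb, against 4.86% of other marked genes (exact adjusted p = 2.61e-25), and 11 of 14 heme genes were (78.6%, exact adjusted p = 1.48e-11). The marked erythroid genes outside this set were Klf1, Epb42, Hbb-bs and Hbb-bh1, named after their values were seen. Liver transcription factors (Gata6, Prox1, Onecut2, Gata4 and Tbx3) and progenitor genes (Lyl1, Runx1, Meis1, Ikzf1 and Kit) had 5 of 19 members each in this set (26.3%, exact adjusted p = 0.00806), of which Gata4, Tbx3, Ikzf1 and Kit were named after their values were seen. Housekeeping genes had 6 of 25 (24%, exact adjusted p = 0.00806), a call that was lost with domains not joined (3 genes), domains joined at 3 kb (3 genes) and domains of a single gene (2 genes). The liver factor call was lost with outermost start sites (4 genes). The progenitor call was lost there too, with the list of replicate 1 alone, and with domains joined at 3 kb (4 genes each). Mesenchymal genes had 3 of 14 (Hand2, Lhx2 and Pdgfra, exact adjusted p = 0.101), cell cycle genes 3 of 20 (Pcna, Aurka and Ccne1, exact adjusted p = 0.216), imprinted genes 2 of 14 (Igf2 and Peg3, exact adjusted p = 0.384) and megakaryocyte genes 1 of 11 (Nbeal2, exact adjusted p = 0.960). Of the genes named here for their lists, Hmbs, Nbeal2, Egfl7, Rpl13a, Rplp0, Pcna, Aurka and Peg3 also lie in domains that hold the start of a neighbouring gene. No marked member of the other 11 lists was among the widest, with an exact adjusted p of 1 for each.

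The globin clusters, mapped after their values were seen, differed between adult and embryonic genes in width, with no test made. The adult genes lay in wide domains, with 10.1 kb at Hba-a1 (9.31 ± 0.890 kb in the replicates, SD, n = 2), 9.60 kb at Hba-a2 (9.47 ± 0.227 kb), 7.21 kb at Hbb-bt (7.14 ± 0.131 kb) and 4.86 kb at Hbb-bs (4.77 ± 0.0537 kb). The domains at Hba-a1 and Hba-a2 also hold the starts of Hbq1b and Hbq1a. In the first of them the peak of highest signal value (29.0, from 32286064 to 32289655) lay at Hbq1b, and the value at Hba-a1 was 11.4. The embryonic gene Hbb-bh1 had 0.453 kb, with 0.522 kb in replicate 2 at the same place and 0.247 kb in replicate 1 at another, and Hba-x, Hbb-y and Hbb-bh2 had no replicated region. The domains at the adult genes were joined from several peaks. In the replicated list they held stretches without a peak, as between 32283438 and 32284384 at Hba-a1 and between 103812814 and 103813582 at Hbb-bt. The promoters of Hba-a1 and Hba-a2 are 98.04% identical, so the regions at this pair are less certain than those at single-copy genes. Copies under 98% identity were not counted, so Hbb-bt and Hbb-bs are not shown to be single-copy.

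**Figure D3:**
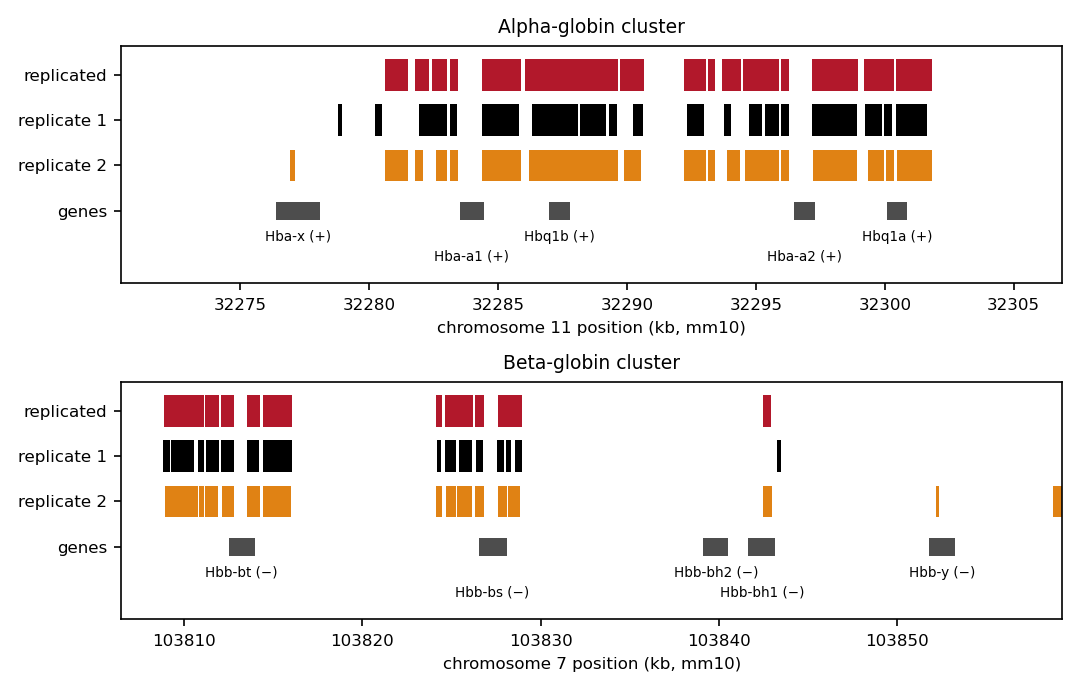
Peaks (bars) of the replicated list, replicate 1 and replicate 2 at the alpha-globin cluster on chromosome 11 and the beta-globin cluster on chromosome 7, with gene bodies in grey and the strand in brackets. Peaks covered 16.2 kb of the alpha-globin window and 10.3 kb of the beta-globin window in the replicated list, mostly in the domains of Hba-a1 with Hbq1b, Hba-a2 with Hbq1a, Hbb-bt and Hbb-bs; the windows were chosen after the values were seen.

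The widest domain lay inside Ank1, on chromosome 8 from 23033247 to 23059672. It spanned 26.4 kb in the replicated list and 27.9 ± 1.38 kb in the replicates (SD, n = 2), and it covers an internal start site, since with the outermost start site alone the width at Ank1 was 1.53 kb. Next were Rbm38, which encodes an RNA-binding protein, with 20.3 kb (chromosome 2, 173018751 to 173039011; 17.0 ± 4.87 kb), and a 16.6 kb domain at Junb, Prdx2, Rnaseh2a and Gm49661 (chromosome 8, 84964193 to 84980753; 16.4 ± 0.158 kb). Lmo2 had 16.2 kb (chromosome 2, 103957110 to 103973276) and, in the replicates, adjoining parts of this stretch (7.48 kb in replicate 1 and 8.95 kb in replicate 2). Zc3hav1 had 16.0 kb and 6.46 ± 0.202 kb, so both were joined over a longer stretch in the replicated list than in either replicate. Epb41, which encodes protein 4.1 of the red cell membrane skeleton, shared a domain of 15.9 kb with Gm10300, and Stradb and Trak2 shared 15.1 kb (8.88 kb in replicate 1 and 16.4 kb in replicate 2). Bmp2k (14.5 kb), Rhof and Setd1b (14.2 kb), Gtpbp1 and Josd1 (13.9 kb), Ell2 (13.8 kb), Klf3, a Krüppel-like transcription factor (13.7 kb), Fech (13.5 kb), Mgst3 (13.3 kb) and Ubac1 (13.1 kb) followed. At Rhof and Setd1b the domain reached 14.3 kb in replicate 2, while replicate 1 had separate domains of 2.01 kb at Rhof and 10.56 kb at Setd1b. At Ubac1 the domain was 13.04 kb in replicate 2 and 6.35 kb in replicate 1. A pair of domains lay in the histone gene cluster of chromosome 13, at Hist1h2ag, Hist1h2ah, Hist1h2bj and Hist1h2bk (12.5 kb) and at Hist1h1b, Hist1h2an, Hist1h2bp and Hist1h3i (12.4 kb). The latter was 2 separate domains in both replicates, of 7.93 kb at Hist1h1b and Hist1h3i and of 3.14 and 3.34 kb at Hist1h2an and Hist1h2bp. The 20 widest ended with Naga, Pheta2 and Smdt1 (12.4 kb), Nadk2 (12.2 kb) and Ppp1r9b (12.1 kb). These widths rest on joining neighbouring peaks. Without it the peak at Ank1 was 15.8 kb, and 10 of the 50 genes with the widest domains were still among the widest 50. The replicated regions with the highest signal values were at Phf12 (97.7), Wdr26 (96.7), Cpox (96.7), Zfand3 (95.9) and Top1 (94.98).

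The replicates shared most of their marked bases. Of the regions of replicate 1, 27683 of 30866 (89.7%) shared at least 1 bp with replicate 2, and 26069 of 33949 (76.8%) of those of replicate 2 did with replicate 1, while random placements gave at most 3.66% and 3.20%. The shared bases were 80% of the bases in either list. Across the 24275 joint regions, which are not independent replicates, Spearman's rho between the replicates was 0.955 for the signal value and 0.971 for the width. Of the replicated list 93.5% of regions overlapped both replicate lists, 94.9% that of replicate 1 and 98.5% that of replicate 2, and 43 overlapped neither. The replicated list was derived from the replicate lists and the pool. Its overlap with them, and that of the pooled regions it left out, describes how it was made and is no further evidence of agreement. The pooled list held another 9297 regions, with a median width of 226 bp and a median signal value of 2.73, of which 77 overlapped both replicates. In total 68.8% of pooled regions overlapped both. These shares depend on the overlap required: with 50% of both regions 70.5% of replicate 1 and 64.1% of replicate 2 were shared.

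Regions of 1 replicate only were narrow and mostly away from promoters. Replicate 1 had 3183 of them (10.3% of its regions and 2.15% of its bases), with a median width of 224 bp against 935 bp for its shared regions and a median signal value of 3.10 against 8.76. Replicate 2 had 7880 (23.2% and 5.16%), with 229 bp against 1125 bp and 3.20 against 11.9. Protein-coding starts lay within 1 kb of 22.4% and 22.3% of these regions, against 59.9% and 61.2% of shared ones, and introns held 43.5% and 42.4%. Of these 3183 and 7880 regions, only 5.15% and 13% had a q-value score of at least 5. With both lists cut at that score before comparing, 797 and 3261 regions were in 1 replicate only. These counts therefore include regions that were shared in the full lists and whose partner fell under the cut. Regions in 1 replicate only numbered 1505 and 3331 with regions joined at 1 kb, and 9095 and 12178 with 50% overlap.

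Few genes were marked in a single replicate. Protein-coding genes with a region in the list of replicate 1 alone numbered 99, and 270 had one in replicate 2 alone, against 14416 in both. No test between the replicates was made with 1 sample on each side. The genes with the highest signal values were Nup160, 1700017N19Rik, Gm9821, Gmnc and Btnl9 for replicate 1 and Gm28035, Apof, Gm30191, Rs1 and Ggt1 for replicate 2. For 4 of the first 5 (all but Gmnc) and all of the second 5, the region of highest signal value also overlapped a region of the other replicate, which missed the 1 kb window there. The same was true of 8 of the 99 and 12 of the 270 genes. In the replicated list 23.2% of the 99 and 37.8% of the 270 were marked. For 17 of the 99 and 39 of the 270 genes the other replicate had a region within 2.5 kb of a start site, so that for these genes the call rested on the 1 kb window.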

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

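Outside the chromosomes that the comparisons use, the replicated list held 11 peaks on 6 scaffolds, with a median width of 638 bp and a highest signal value of 59.1. The list of replicate 1 had 16 such peaks and that of replicate 2 had 15. They were singled out because they are signal in data the comparisons leave out, and they were not assigned to genes.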

How the results depend on the processing

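Of 629 alternative values for the main results, 535 kept their direction and their side of the threshold, kept their place against the central 95% of random lists, or stayed within the spread allowed for values with no test. All 8 alternative values for replicate overlap left that spread. So did all 6 for the series lists against the replicates and all 6 for regions in 1 replicate only. Domains of a single gene were an alternative chosen after seeing the data. Depth is unknown, so what it limits could not be computed. No paired analysis was possible because there is 1 group. The share of replicated regions at promoters stayed above all random placements under all 7 alternatives (49.8 to 67.8%; 52.2 to 56.0% without either replicate), and counts of genes marked in 1 replicate stayed within 1.5 times (77 to 109 and 273 to 342). For single genes, width was varied at the first gene of each of the 20 widest domains and at the 5 of highest signal value, and 153 of 225 values stayed within 1 SD of the replicates. The causes of the changes below were not tested.

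With 50% overlap of both regions, a q-value score of at least 5 and regions joined at 1 kb, the shared regions of replicate 1 were 70.5, 96.2 and 93.3%, those of replicate 2 were 64.1, 85.6 and 86.2%, replicated regions in both were 81.1, 79.4 and 95.9%, and pooled regions in both were 59.5, 77.3 and 82.6%. Regions in replicate 1 only numbered 9095, 797 and 1505 and those in replicate 2 only 12178, 3261 and 3331. The bases shared of all were 83.3% at the q-value score and 80.7% joined.

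With a 500 bp window the heme (93.3%), imprinted (93.3%) and plasma protein (86.4%) shares missed the threshold, leaving 5 lists with a higher share. With the pooled list heme (93.3%) and imprinted (93.3%) shares missed it, and endothelial (100%) and patterning factor (96.7%) shares passed it. Patterning factors also passed it with a 2.5 kb window (90%). With outermost start sites the imprinted share (73.3%) missed it and the lymphoid share (25%) passed it as lower, and the macrophage share did so at the q-value score (40%). Against CpG-matched lists the unchanged shares of heme (93.3%), adult hepatocyte (26.7%) and muscle (20%) genes missed it. The shares of housekeeping (100%) and cell cycle (100%) genes also missed it after adjustment, with little room for a higher share as all members were marked already. Those of megakaryocyte (73.3%) and endothelial (88.2%) genes passed it, that of clotting and complement genes (57.1%) turned from lower to higher, and 1 list was left with a lower share. Without passing the threshold, direction also turned there for macrophage (45%) and lymphoid (45%) genes, to higher, and for patterning factors (83.3%), to lower, and with the pooled list for clotting and complement genes (67.9%), to higher. Without either replicate, endothelial shares were 88.2 to 100%, patterning factor shares 86.7 to 93.3% and mesenchymal shares 65 to 70%, lower than other genes without replicate 2, with 9 to 10 lists higher and 3 lower. Over the 8 alternatives, exact or permutation adjusted p ranged from 0.0254 to 0.074 for heme, 0.00133 to 0.0794 for plasma protein, 3.72e-05 to 0.363 for adult hepatocyte, 0.0048 to 1 for clotting and complement, 0.010 to 1 for megakaryocyte, 0.0381 to 0.903 for macrophage, 0.00265 to 1 for lymphoid, 0.00282 to 0.528 for endothelial, 1.69e-04 to 0.0717 for muscle, 9.73e-04 to 0.176 for patterning factor, 2.59e-04 to 0.0717 for housekeeping, 5.07e-04 to 1 for cell cycle and 0.0103 to 0.488 for imprinted genes.

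By signal value in place of width, percentiles were 51.5 for erythroid, 97.3 for heme and 17.3 for germline genes, now inside the central 95%, and turned from above to below for liver transcription factors (0.61) and progenitor genes (0.53). They fell below it for plasma protein (0), megakaryocyte (0.08), macrophage (0), lymphoid (0.28), endothelial (0.02), mesenchymal (0.01), bile duct (1.45) and imprinted (0.2) genes. With the pooled list, width fell below it for adult hepatocyte (0), macrophage (0.09), bile duct (0.705) and muscle (2.33) genes. Muscle genes were below it with a 2.5 kb window (2.38) and macrophage genes with domains not joined (0.09). Imprinted genes rose above it with domains not joined (98.5) and joined at 3 kb (98.9). With domains of a single gene, adult hepatocyte genes were below it (1.97) and patterning factors inside it (8.99). Without either replicate, percentiles ranged from 0.065 to 4.44 for macrophage genes, 0.06 to 2.53 for patterning factors and 94.3 to 97.6 for imprinted genes.

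Among the widest 5%, with outermost start sites liver transcription factors (4 members) and progenitor genes (4) missed the threshold. Progenitor genes also missed it with domains joined at 3 kb (4) and had 4 to 5 members without either replicate. Housekeeping genes missed it with domains not joined (3), joined at 3 kb (3) and of a single gene (2). Cell cycle genes passed it with the pooled list (4), domains not joined (5) and domains of a single gene (5), and mesenchymal genes with the pooled list (4). Without passing it, direction turned to lower for megakaryocyte genes with domains not joined (0), joined at 3 kb (0) and of a single gene (0). It turned to higher for lymphoid genes with the pooled list (1), domains joined at 3 kb (2) and without replicate 2 (0 to 1 without either replicate), for muscle genes with domains not joined (1) and for patterning factors joined at 3 kb (2). Erythroid and heme genes passed it under all 10 alternatives (exact adjusted p from 2.49e-25 to 2.05e-13 and 1.44e-11 to 3.32e-04).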

Other observations

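The groups in this paragraph and the next were chosen after values were seen. X-linked genes were marked in 469 of 948 cases (49.5%, 95% interval 46.2 to 52.7), with a median signal value of 29.8, against 14053 of 20780 autosomal genes (67.6%, interval 67.0 to 68.3) with a median of 50.1. On chromosome Y 4 of 183 genes were marked, namely Ddx3y, Eif2s3y, Kdm5d and Uty, in both replicates. Of 11 gene families taken by symbol, the Hist1 histone genes had 47 of 54 members marked and a median domain of 8.23 kb, ribosomal protein genes 73 of 76 (3.88 kb), proteasome subunits 38 of 39 (2.67 kb) and Zfp zinc finger genes 323 of 365 (1.92 kb). These medians are over genes, so a domain shared by several Hist1 genes enters theirs several times. Hox genes were marked in 9 of 11 (Hoxa), 7 of 10 (Hoxb), 6 of 9 (Hoxc) and 7 of 9 (Hoxd) cases, keratins in 7 of 49, olfactory receptors in 3 of 1134 (Olfr1033, Olfr56 and Olfr94) and vomeronasal receptors in 1 of 330 (Vmn1r4, in a domain shared with a neighbour). Copied promoters were not counted separately on chromosomes X and Y or in these families. Both pools mix the sexes, so X-linked and autosomal genes were not compared at equal copy number. Low shares in these groups are therefore not shown to be absence of the mark.

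Long noncoding RNA genes were marked in 2561 of 10143 cases (25.2%), 750 of them in a domain without a protein-coding start. The widest of these were Mir142hg (11.03 kb), the host of the blood cell microRNA miR-142, Dleu2 (10.1 kb) and Malat1 (9.55 kb), and Neat1 had 9.16 kb. Imprinted noncoding genes had 5.24 kb (H19), 3.43 kb (Meg3), 3.31 kb (Kcnq1ot1) and 2.14 kb (Airn), and Xist had 4.18 kb. No annotated start site lay within 1 kb of 6225 domains, with a median of 0.709 kb and the widest, 10.3 kb, on chromosome 13 from 23497571 to 23507886.

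The tests in this paragraph were chosen after related values were seen. Of 40 marked erythroid and heme genes 33 (82.5%) were among the widest 5% of domains. Several protein-coding genes with 1 wide domain in common and the joining of nearby peaks were argued against as the whole cause, since 27 of 33 (81.8%) were there among domains of a single gene and 27 of 40 (67.5%) with peaks not joined, although that share was lower. Starts of noncoding genes, or of genes with a wider domain elsewhere, were not counted for the former. Stronger signal within 1 kb of the start sites was also argued against, as the median width lay at percentile 100 of 10000 random lists matched on it. The match left out peaks of a domain further from the start sites, so stronger signal there stays open. Local accessibility, fragment length and the share of erythroid cells in the tissue were not tested, and no biological explanation was tested, as the design has 1 group.

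CpG-rich promoters without a replicated region numbered 184, against 9879 with one. A candidate explanation, prompted by Slc25a37, is that reads from copied sequence were not assigned. Of the 184, 57 (31.0%, interval 24.4 to 38.2) had a near-identical copy elsewhere, against 32 of the 9879 (0.324%, interval 0.222 to 0.457). Among promoters not rich in CpG, 979 of 7201 without a region (13.6%) and 16 of 4647 with one (0.344%) had such a copy. Such copies were thus far more frequent among promoters without a region but were not found for most of the 184. Near-identical copies of this length are argued against as the whole cause and stay open for the 57. Shorter or less alike copies and copies on scaffolds were not counted, so copied sequence of those kinds stays open for the others too.

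Regions in 1 replicate only were also counted by signal value, after their values were seen. Of the regions at or above the median signal value, 15436 of 15437 in replicate 1 and 16955 of 16977 (99.9%) in replicate 2 were shared, against 79.4% and 53.7% of those under the median. This restates the low signal values of these regions and tests no explanation of them. Depth is unknown and stays open.

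A hypothesis that replicated regions away from start sites carry sites for lineage factors was tested on 8671 regions against 12837 flanks 1 kb away. Per kb, GATA sites had a ratio of 0.944 (0.745 for the reversed motif), so they were not denser than in the flanks. As the regions are richer in G and C (51.1% against 45.7%), an effect of base composition cannot be told apart from one of the sites. HNF4 sites had a ratio of 0.898 (1.06 reversed), and MEF2 sites, as a muscle control, had 0.892 (0.725 reversed) with 109 sites in the regions. Neither was denser than in the flanks. GATA and MEF2 sites had ratios above those of their reversed motifs and HNF4 sites one below, but the reversed HNF4 motif can hold a CpG and the motif itself cannot, so it is no matched control. For these 3 motifs the expected ratios were stated before counting. Another 3 (CEBP, HNF1 and ETS) were counted without a stated expectation, and all 6 also at start sites. CEBP sites had a ratio of 0.936 (0.831 reversed), HNF1 sites 0.826 (0.541 reversed) and ETS sites 3.48 (1.11 reversed). The reversed CEBP motif can hold more CpG than the motif itself, so it is no matched control either. At start sites the ratios were 0.613 for GATA, 0.832 for HNF4, 0.690 for MEF2, 0.821 for CEBP, 0.655 for HNF1 and 6.96 for ETS. ETS was the only motif denser than in the flanks, but its motif always holds a CpG and the reversed motif only in 1 of its 2 forms, so it is no matched control.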
